A study of Homo sapiens with 16 samples.

How the data were processed

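Total RNA was sequenced from 16 libraries of 2 human breast cancer cell lines, MCF-7 (estrogen receptor positive) and SK-BR-3 (ERBB2 amplified). Each line was transduced with lentiviral short hairpin RNAs in sequence, first a scrambled control (shSCR) or shADAR1 and then shSCR or shDHX9, with protamine at 10 ug per ml and selection in puromycin and hygromycin. This gives 4 groups per line, namely control (shSCR + shSCR), ADAR1 knockdown (shADAR1 + shSCR), DHX9 knockdown (shSCR + shDHX9) and double knockdown (shADAR1 + shDHX9), with 2 replicate libraries in each. The labels do not say whether replicates are separate cultures, so p-values here measure the spread between these libraries alone. They also do not give the number of hairpins per target, so an effect of one hairpin cannot be set apart from an effect of its target.

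Ribosomal RNA was removed enzymatically, complementary DNA was primed with random hexamers, and the libraries were sequenced as read pairs. Per the labels, the submitters made the read files with bcl2fastq, aligned them to GRCh38 with STAR 2.7.9a and counted them per gene with featureCounts 2.0.3 of Subread. Both deposited tables hold raw counts that no normalization had touched. The program that counted repeat subfamilies, the strand setting and the annotation release are not stated. The gene table has 60871 lines for 60671 Ensembl gene IDs, and the other 200 lines repeat an ID with equal counts and were dropped. Among its counts above 0, 58.7% to 61.3% per library were even, against 45.2% to 47% in the element table, as when both mates of a pair are counted in the first. The element table has 62703 gene lines and 1180 repeat subfamilies. Total gene counts per library were 19203383 to 47016545, and repeat subfamilies held 15.5% to 22.6% of the element table.

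Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): the default expression filter by group with a minimum count of 10, which kept 26867 gene IDs, TMM scaling (factors 0.926 to 1.05), and robust quasi-likelihood F tests, two-sided, in 1 fit of all 16 libraries with a coefficient for each of the 8 groups and 8 residual degrees of freedom. Adjusted p is Benjamini-Hochberg, with a threshold of 0.05. Each line had 6 comparisons: each single and the double knockdown against control, the double against each single knockdown, and the interaction, which asks whether the double knockdown differs from the sum of the single ones on the log2 scale. The same changes were also compared between lines, as MCF-7 minus SK-BR-3. The 1115 repeat subfamilies that passed the same filter were tested likewise, scaled by the library sizes and factors of the gene table so that a shift of all elements together stays visible. Levels are given as CPM of the scaled library.

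Gene lists were fixed before the data were examined, as were the tests, most alternative settings and the rule for named genes: interferon-stimulated genes, interferon genes, double-stranded RNA sensing and effector genes, double-stranded RNA binding and editing genes, NF-kB targets, integrated stress response, endoplasmic reticulum chaperones, p53 targets, cell cycle, antigen presentation, estrogen response, cholesterol synthesis, cytosolic ribosomal proteins, hypoxia and glycolysis, mesenchymal and matrix genes, and the identity genes of MCF-7 and of SK-BR-3. The lists were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists of a comparison. Markers of fibroblasts, macrophages, lymphocytes and endothelium were only counted. The named genes are ADAR and DHX9, the 8 largest rises and falls among genes past the threshold with a mean of at least 1 CPM and groups that do not overlap, and the 3 members of each list with the smallest p in each direction. For repeats they are the 5 largest rises and falls with a mean of at least 10 counts, plus the Alu, L1 and endogenous retrovirus families. Of these the text gives mainly the ones whose call held without each library of the line in turn, and names the libraries for the others. Genes named outside the rule were chosen after their values were seen: ISG15, STAT1, DDX58, EIF2AK2, IFITM2, IFNB1, IFNL1, RELB and TNFAIP3 where the rule does not give them, well-known list members given because they did not pass, the genes that DHX9 knockdown changed in both lines, and the genes of counts of 5 or fewer. Gene positions are from GENCODE (GRCh38).

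Whether replicate numbers pair libraries across groups was checked by correlating the log2 difference of replicates 1 and 2 between groups, with a limit of 0.1. The 6 pairs of SK-BR-3 groups gave r of 0.1 to 0.22 (0.257 to 0.765 over genes above 8 CPM), so the value with replicate number as a block stands beside SK-BR-3 results where it changes a call or moves a count by over 1.5 times. The 6 MCF-7 pairs gave 0.0609 to 0.113 (0.068 to 0.545 over genes above 8 CPM). Control with DHX9 knockdown (0.106) and DHX9 with double knockdown (0.113) were above the limit and the others below, so its block is only an alternative. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 11.3 to 35.4), with r of log2 CPM from 0.988 to 0.993.

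Alternatives were RLE size factors, library totals alone, no filter, a filter of 1 CPM in 2 libraries, the replicate block and each cell line alone. Others were DESeq2 1.42.0, an adjusted p under 0.01, the repeats' own totals, leaving out each library in turn, fry, and camera with an estimated correlation. The repeats' own totals are the summed repeat counts of each library, with TMM factors computed over repeats. That scaling centres the repeats, so it cannot show a shift of all subfamilies together. Where leaving out a library left a group with 1, that library was assumed to vary like the other groups. On simulated counts of this design the edgeR test found 52% of 2-fold and 89% of 4-fold changes between MCF-7 groups, and 18% and 69% in the interaction. For SK-BR-3 these were 57% and 94%, and 18% and 84%. The changed genes were drawn from those above 1 CPM in the control, so these shares do not cover genes of lower expression. Few genes were changed, and replicate differences shared across groups were not simulated, so the shares may differ in the real comparisons. Unchanged genes made up 4 of 155 calls between SK-BR-3 groups. They made up 10 of 151 between MCF-7 groups, and 10 of 97 and 11 of 113 in the interactions, each above the 0.05 aimed at. A fold against a group with 0 counts is a lower bound from a floor of 3 counts per library, and with 1 to 3 counts the ratio is given with its 95% interval. Floors and intervals cover counting error only, with each count taken as independent. If both mates of a pair were counted, as the share of even counts may reflect, the bounds are too high and the intervals too narrow. Groups of 2 allow no exact test of a single value below 0.05 and no outlier test. The labels give no batch.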

Results

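The series measured gene and repeat-element RNA in 16 libraries of MCF-7 and SK-BR-3 breast cancer cells after knockdown of ADAR1, of DHX9, or of both, with 2 libraries per group and line. ADAR1, encoded by ADAR, converts adenosine to inosine in double-stranded RNA, and its long form is itself induced by interferon. DHX9 is an RNA helicase that unwinds structured RNA. By its title the series asks whether loss of both proteins makes breast cancer cells respond as if infected by a virus. Total gene counts per library ranged from 19203383 to 47016545. In what follows, levels are mean CPM ± SD of 2 libraries, and changes are log2 fold changes from edgeR ± SE. The SE was derived from the test, as the size of the change over the square root of its F statistic. Adjusted p covers 26867 genes unless another test is named.

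ADAR (ENSG00000160710, chromosome 1, 154581695 to 154628013, minus strand) fell with shADAR1 alone from 367 ± 14.6 to 126 ± 6.08 CPM in MCF-7 (-1.54 ± 0.13, adjusted p = 2.26e-06) and from 466 ± 9.86 to 88.2 ± 3.69 in SK-BR-3 (-2.40 ± 0.14, adjusted p = 7.4e-10). DHX9 (ENSG00000135829, chromosome 1, 182839347 to 182887982, plus strand) fell with shDHX9 alone from 263 ± 6.32 to 54.7 ± 6.03 CPM in MCF-7 (-2.27 ± 0.20, adjusted p = 1.21e-06) and from 284 ± 40.3 to 72.5 ± 17.8 in SK-BR-3 (-1.97 ± 0.20, adjusted p = 2.01e-05). In the double knockdowns DHX9 stood at 65.2 ± 10.8 CPM in MCF-7 (-2.01 ± 0.20, adjusted p = 3.3e-07) and 63.4 ± 10.6 in SK-BR-3 (-2.16 ± 0.20, adjusted p = 1.88e-06). ADAR stood at 110 ± 9.63 CPM in the SK-BR-3 double knockdown (-2.09 ± 0.13, adjusted p = 9.23e-09) but at 276 ± 7.08 in that of MCF-7 (-0.41 ± 0.13, adjusted p = 0.0329). That last call was lost without any 1 of the 4 libraries compared, with library totals alone (-0.29, adjusted p = 0.122) and with no filter (adjusted p = 0.0806). Against the ADAR1 knockdown, ADAR was higher in the MCF-7 double knockdown (1.13 ± 0.13, adjusted p = 3.07e-06), while SK-BR-3 gave 0.31 (adjusted p = 0.178).

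**Figure D1:**
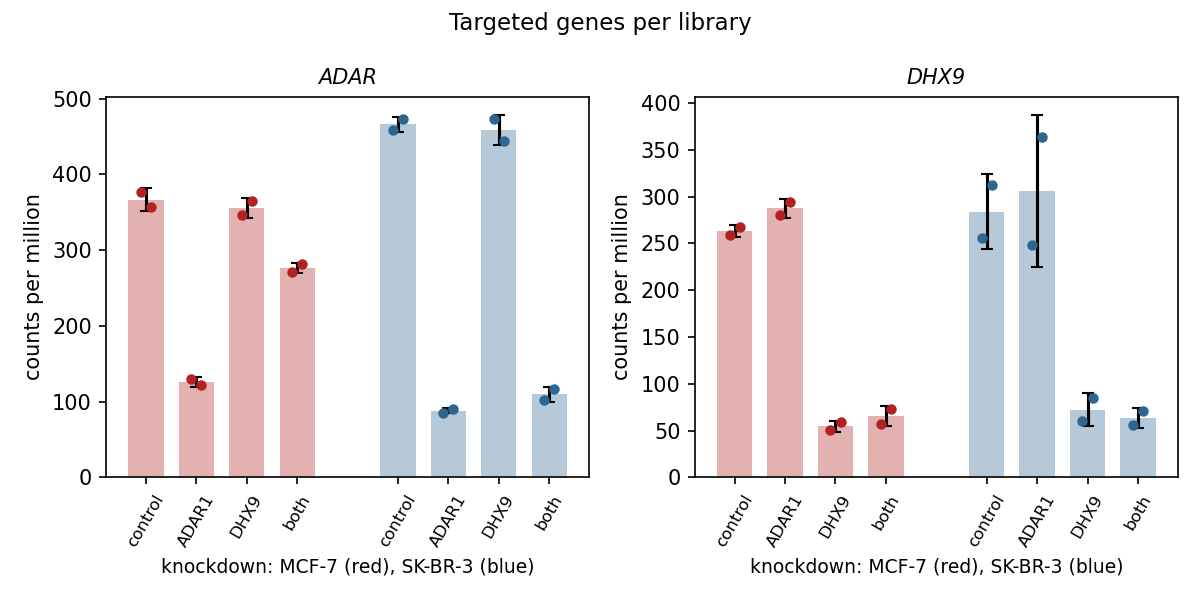
ADAR and DHX9 in CPM by group and line; bars are means, error bars SDs and points the 2 libraries of each group. In the MCF-7 double knockdown the ADAR points sit at 271 and 281 CPM, between the ADAR1 knockdown (122 and 130) and the control (357 and 377).

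ADAR1 knockdown alone left most of the MCF-7 transcriptome without a detectable change: 4 genes passed. Besides ADAR itself, KLK6, a secreted serine protease, rose from 3.92 ± 0.809 to 13.7 ± 2.68 CPM (1.81 ± 0.28, adjusted p = 0.0244). OAS2, an interferon-induced enzyme activated by double-stranded RNA, rose from 0.963 ± 0.305 to 3.15 ± 0.722 CPM (1.73 ± 0.26, adjusted p = 0.0146), and LAMB3, a laminin chain, from 30.6 ± 0.408 to 63.3 ± 0.995 CPM (1.05 ± 0.17, adjusted p = 0.0244). OAS2 was the 1 of 58 interferon-stimulated genes that passed (5 adjusted over the list alone), and the list median was 0.43 (0.40 without 7 genes near 0 counts). Camera called that list higher (adjusted p = 1.63e-15), but not with an estimated correlation (adjusted p = 0.117). Cell cycle genes had a median of 0.26 with 0 of 44 passing (camera adjusted p = 2.88e-13; adjusted p = 0.117 with an estimated correlation). KLK6 and LAMB3 each lost their call without any of the 4 libraries compared, and OAS2 without replicate 2 of the knockdown or of the control. The count of 4 became 2 and 1 without replicates 1 and 2 of the knockdown, 8 and 1 without replicates 1 and 2 of the control, and 59 in DESeq2.

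DHX9 knockdown alone raised 128 MCF-7 genes and lowered 165, led by several that control cells barely expressed. DESeq2 gave 237 higher and 305 lower, and the replicate block 448 and 681. C19orf73 (ENSG00000221916, chromosome 19, 49118402 to 49119143) rose from 1.78 ± 0.0713 to 39.5 ± 7.52 CPM (4.47 ± 0.32, adjusted p = 9.77e-08). BIN2 (ENSG00000110934, chromosome 12, 51281038 to 51324668), a membrane-shaping protein of blood cells, rose from 1.41 ± 0.147 to 21.4 ± 3.64 CPM (3.93 ± 0.34, adjusted p = 1.21e-06). RASGRP1, an activator of Ras, rose from 12.5 ± 2.49 to 69.5 ± 16 CPM (2.48 ± 0.23, adjusted p = 1.3e-06). C1orf54 (2.81 ± 0.32, adjusted p = 5.79e-05) and NIBAN3 (2.48 ± 0.36, adjusted p = 0.000738) rose too, and the chemokine gene CCL25 went from 2 to 311 counts (ratio 158, 95% interval 43.4 to 1310). That interval is too narrow if both mates of a pair were counted. Among the falls, PGM1, an enzyme of glycogen and glucose metabolism, went from 10.3 ± 2.36 to 2.86 ± 1.04 CPM (-1.79 ± 0.25, adjusted p = 0.00048).

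Interferon-stimulated genes as a list did not pass in this comparison (median 0.16, camera adjusted p = 0.102): OAS2 rose (1.40 ± 0.26, adjusted p = 0.00626) and IFITM3 and IFITM2, which restrict virus entry, fell (-0.97 ± 0.16, adjusted p = 0.00234, and -0.88 ± 0.15, adjusted p = 0.0042). OAS2 lost its call without replicate 1 of the knockdown or replicate 2 of the control, IFITM3 without replicate 2 of either, and IFITM2 without either knockdown library or control replicate 2. Of 18 antigen presentation genes, 2 fell (7 adjusted over the list alone; median -0.35, camera adjusted p = 2.72e-05, adjusted p = 0.35 with an estimated correlation). Endoplasmic reticulum chaperones had a median of -0.36 with 0 of 20 passing (camera adjusted p = 0.000106, adjusted p = 0.397 with an estimated correlation), and 1 of 24 hypoxia and glycolysis genes fell (camera adjusted p = 0.0034, adjusted p = 0.35 with an estimated correlation). The 293 genes became 100 and 61 without replicates 1 and 2 of the knockdown and 38 without control replicate 2.

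In the MCF-7 double knockdown 57 of 58 interferon-stimulated genes rose, with a median log2 change of 4.29. OAS2 (ENSG00000111335, chromosome 12, 112978395 to 113011723) rose from 0.963 ± 0.305 to 242 ± 34.4 CPM (8.01 ± 0.26, adjusted p = 9.6e-15). MX1 (ENSG00000157601, chromosome 21, 41420020 to 41470071), an antiviral GTPase, rose from 4.91 ± 0.15 to 287 ± 42.4 CPM (5.87 ± 0.21, adjusted p = 2.28e-14), and OAS3 (ENSG00000111331, chromosome 12, 112938051 to 112976460) from 39.4 ± 5.46 to 1120 ± 93.6 CPM (4.83 ± 0.17, adjusted p = 1.47e-14). ISG15, a ubiquitin-like protein, reached 1330 ± 213 CPM against 99.2 ± 1.02 (3.75 ± 0.42, adjusted p = 0.000137), and STAT1, which carries interferon signals to the nucleus, 949 ± 244 against 102 ± 2.26 (3.22 ± 0.17, adjusted p = 1.49e-11). CXCL10, a chemokine that attracts T cells, was at least 79.5-fold higher, at 6.92 ± 0.916 CPM against 0 counts in the control. This bound, like the others of its kind, is lower if both mates of a pair were counted. The member that did not pass was IFITM2 (-0.37 ± 0.15, adjusted p = 0.103), whose reads are hard to tell from those of its close relatives. Camera gave the list an adjusted p of 2.9e-218 (4.12e-05 with an estimated correlation).

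Interferon genes themselves rose in 4 of 5 tested cases. IFNL1, a type III interferon, went from 0.231 ± 0.0142 to 16.9 ± 3.84 CPM (6.16 ± 0.56, adjusted p = 5.92e-07), and the near-identical IFNL2 and IFNL3 to 11.1 ± 0.318 and 9.83 ± 0.669 CPM (6.90 ± 0.67, adjusted p = 2.2e-07, and 4.28 ± 0.54, adjusted p = 7.15e-06). IFNB1 (ENSG00000171855, chromosome 9, 21077104 to 21077942), the type I interferon of most cells, had 150 counts against 4 in the control (5.36 ± 1.25, adjusted p = 0.0102). Its level differed between the 2 libraries, 1.04 and 4.51 CPM, and the call was lost without replicate 2 of the double knockdown or of the control. Of 20 sensing and effector genes, 15 rose: IFIH1, the sensor MDA5, reached 174 ± 38.8 CPM against 11.2 ± 0.809 (3.96 ± 0.26, adjusted p = 8.55e-10). DDX58, the sensor RIG-I, reached 236 ± 93 against 8.8 ± 1.42 (4.75 ± 0.29, adjusted p = 1.14e-09), and EIF2AK2, the kinase PKR, 250 ± 45.7 against 44.8 ± 4.05 (2.48 ± 0.17, adjusted p = 8.55e-10). MAVS, the adaptor of both sensors, fell (-0.58 ± 0.13, adjusted p = 0.00392), a call lost without double knockdown replicate 2 or control replicate 1. Camera gave adjusted p of 1.79e-09 for the interferon genes (0.00343 with an estimated correlation) and 2.04e-47 for the sensing genes (4.99e-05 with an estimated correlation).

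**Figure D2:**
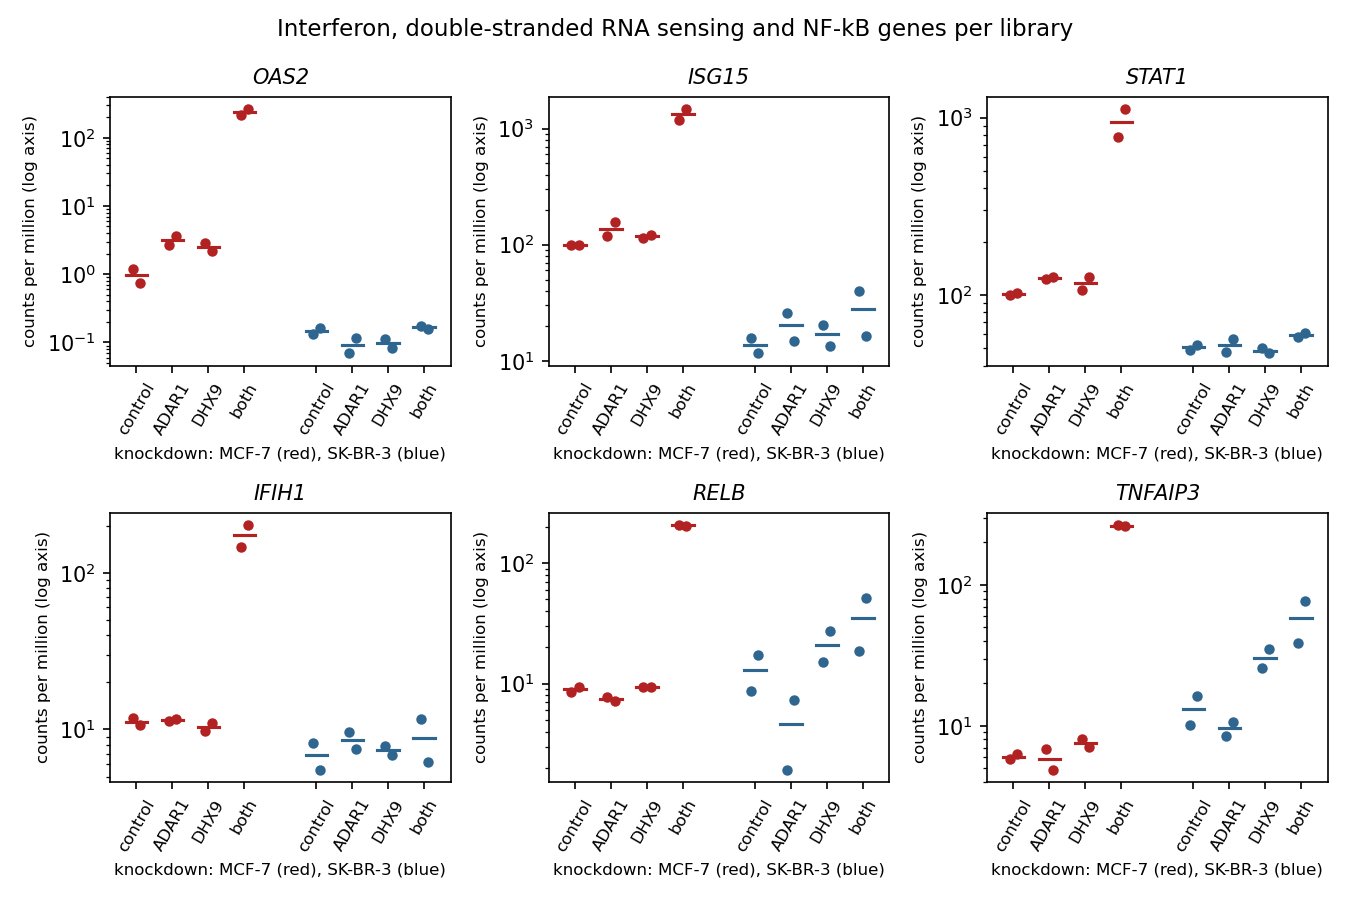
CPM on a log axis of 6 immune genes in each of the 16 libraries; points are libraries and bars group means. OAS2 sits at 218 and 266 CPM in the MCF-7 double knockdown, under 4 CPM in every other MCF-7 library, and under 0.2 CPM in all SK-BR-3 libraries.

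NF-kB targets and antigen presentation genes rose in the same MCF-7 cells. Of 31 NF-kB targets 28 rose and 0 fell (median 4.52, or 4.37 with genes at 0 counts taken at their bound; camera adjusted p = 7.79e-68, 0.000282 with an estimated correlation). TNFAIP2 (ENSG00000185215, chromosome 14, 103121476 to 103137439) went from 6.28 ± 0.805 to 396 ± 9.97 CPM (5.98 ± 0.21, adjusted p = 1.16e-14). CSF1, a growth factor for macrophages, went from 2.83 ± 0.114 to 113 ± 1.99 CPM (5.32 ± 0.26, adjusted p = 4.34e-12), the transcription factor gene IRF1 from 9.18 ± 1.58 to 219 ± 7.21 CPM (4.57 ± 0.25, adjusted p = 2.12e-11), and TNFAIP3, which dampens NF-kB signalling, from 6.05 ± 0.317 to 263 ± 4.57 CPM (5.44 ± 0.33, adjusted p = 1.04e-08). CCL2, a chemokine that attracts monocytes, was at least 71.5-fold higher. Of 18 antigen presentation genes 15 rose and 1 fell (median 1.36, camera adjusted p = 2.59e-41, 0.000282 with an estimated correlation). NLRC5, the activator of MHC class I genes, rose from 1.76 ± 0.0372 to 84.6 ± 8.57 CPM (5.58 ± 0.19, adjusted p = 1.16e-14), the immunoproteasome subunit PSMB9 from 0.634 ± 0.249 to 38.3 ± 4.2 CPM (5.96 ± 0.29, adjusted p = 3.4e-12), and the peptide transporter TAP1 from 30.2 ± 7.75 to 279 ± 32.7 CPM (3.20 ± 0.19, adjusted p = 8.98e-11). The chaperone gene CALR fell (-0.87 ± 0.19, adjusted p = 0.00328), a call lost without replicate 2 of either group.

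Stress response genes rose in part. Of 35 integrated stress response genes 11 rose and 0 fell, among them PPP1R15A, which restores translation after stress, from 34.7 ± 1.56 to 239 ± 13.7 CPM (2.79 ± 0.25, adjusted p = 4.23e-07), the amino acid transporter gene SLC7A5 from 247 ± 41.8 to 834 ± 19.9 CPM (1.76 ± 0.18, adjusted p = 5.7e-07) and VEGFA, the vessel growth factor, from 76.9 ± 13.4 to 228 ± 3.63 CPM (1.57 ± 0.19, adjusted p = 4e-06). Camera called this list higher (adjusted p = 3.14e-10), but not with an estimated correlation (adjusted p = 0.28). Of 21 mesenchymal and matrix genes 9 rose and 3 fell (camera adjusted p = 2.2e-05, 0.0248 with an estimated correlation), with SNAI1, a repressor of epithelial genes, going from 2.62 ± 0.319 to 26.7 ± 0.531 CPM (3.34 ± 0.22, adjusted p = 6.36e-10) and SERPINE1 from 2.58 ± 0.782 to 35.1 ± 5.8 CPM (3.78 ± 0.34, adjusted p = 1.27e-07). The 3 that fell were VIM (-1.46 ± 0.33, adjusted p = 0.00405), COL1A1 (-0.77 ± 0.19, adjusted p = 0.00687) and ACTA2 (-1.22 ± 0.38, adjusted p = 0.0324). How these 3 calls fared without single libraries is not given here. The p53 targets went both ways, 4 higher and 9 lower of 28 (camera adjusted p = 0.143): PMAIP1, which promotes apoptosis, rose (2.05 ± 0.29, adjusted p = 3.28e-05), BAX, of the same family, fell (-0.83 ± 0.14, adjusted p = 0.000301), and MDM2 (-0.06, adjusted p = 0.869) and CDKN1A (0.30, adjusted p = 0.271) did not pass.

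Among the genes that fell in the MCF-7 double knockdown were some of growth, secretion and metabolism. Of 44 cell cycle genes 21 fell and 0 rose (30 fell adjusted over the list alone). The proliferation marker MKI67 went from 389 ± 30.5 to 229 ± 10.9 CPM (-0.76 ± 0.13, adjusted p = 0.000381). Of 75 ribosomal protein genes 27 fell, RPS3 among them (-0.81 ± 0.17, adjusted p = 0.00197). Of 20 endoplasmic reticulum chaperones 12 fell, such as the disulfide isomerase gene PDIA6, from 192 ± 53.7 to 96.8 ± 4.88 CPM (-0.99 ± 0.17, adjusted p = 0.000391). Of 24 cholesterol synthesis genes 9 fell, such as TM7SF2, a sterol reductase gene, from 415 ± 84.8 to 131 ± 11.2 CPM (-1.66 ± 0.16, adjusted p = 1.62e-07). The medians were -0.47, -0.40, -0.62 and -0.51, and camera gave adjusted p of 5.45e-10, 6.08e-11, 1.11e-06 and 1.65e-06. None of these 4 calls held with an estimated correlation (adjusted p = 0.11, 0.359, 0.212 and 0.235). With library totals alone the falls numbered 13 of 44, 17 of 75, 10 of 20 and 8 of 24.

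Estrogen response genes split in the MCF-7 double knockdown, with 3 of 24 higher and 7 lower (camera adjusted p = 0.218). ESR1, the estrogen receptor gene, fell from 567 ± 91 to 248 ± 14.7 CPM (-1.19 ± 0.16, adjusted p = 1.28e-05), RET, a receptor kinase gene, from 360 ± 100 to 122 ± 1.65 CPM (-1.56 ± 0.23, adjusted p = 9.44e-05) and TFF3 from 72.5 ± 1.9 to 16.6 ± 3.95 CPM (-2.13 ± 0.23, adjusted p = 3.36e-06). The growth factor gene AREG rose (1.47 ± 0.22, adjusted p = 0.000164), as did PDZK1 (1.95 ± 0.34, adjusted p = 0.000334). PGR stood at -0.01 (adjusted p = 0.997). Hypoxia and glycolysis genes had 3 higher and 3 lower of 24, a median of -0.10 that turned to 0.02 with library totals alone, a mean of 0.03 and a camera test in the upward direction (adjusted p = 0.671). Double-stranded RNA binding and editing genes had 2 higher and 5 lower of 23, including ADAR and DHX9 (camera adjusted p = 0.0909), and ADARB1, a second editing enzyme gene, fell from 73.1 ± 1.66 to 39.1 ± 0.571 CPM (-0.90 ± 0.17, adjusted p = 0.000969). MCF-7 identity genes had 1 higher and 1 lower of 8 (camera adjusted p = 0.671), and SK-BR-3 identity genes 1 lower of 8 (camera adjusted p = 0.189). The largest falls among the named genes included CHST1, a sulfotransferase gene, from 15.7 ± 2.22 to 1.22 ± 0.431 CPM (-3.67 ± 0.40, adjusted p = 1.26e-06) and NYNRIN from 47.3 ± 1.69 to 5.24 ± 0.111 CPM (-3.17 ± 0.30, adjusted p = 2.03e-07).

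The whole comparison had 1857 genes higher and 2237 lower, 1277 and 814 of them by at least 2-fold. The libraries of the MCF-7 double knockdown also stood apart in composition: 7SL RNA took 2.06% ± 0.0537 of gene counts against 1.48% ± 0.00566 in the control, and mitochondrial genes 2.51% ± 0.14 against 3.68% ± 0.187. Among markers of other cell types, CD79A, a B cell receptor subunit, rose to 5.49 ± 1.74 CPM from 0.663 ± 0.0516 (3.04 ± 0.49, adjusted p = 0.000142), while ERG, an endothelial transcription factor gene, fell to 0.153 ± 0.0101 CPM from 1.76 ± 0.273 (-3.48 ± 0.46, adjusted p = 1.4e-05). By marker list, 1 rose and 1 fell of 5 fibroblast genes, 1 of 2 macrophage genes and 1 of 2 lymphocyte genes rose, and 2 rose and 2 fell of 5 endothelial genes. With library totals alone the split was 2428 higher and 1562 lower. The 4094 genes became 2438 and 2097 without replicates 1 and 2 of the double knockdown and 1952 without control replicate 2.

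**Figure D3:**
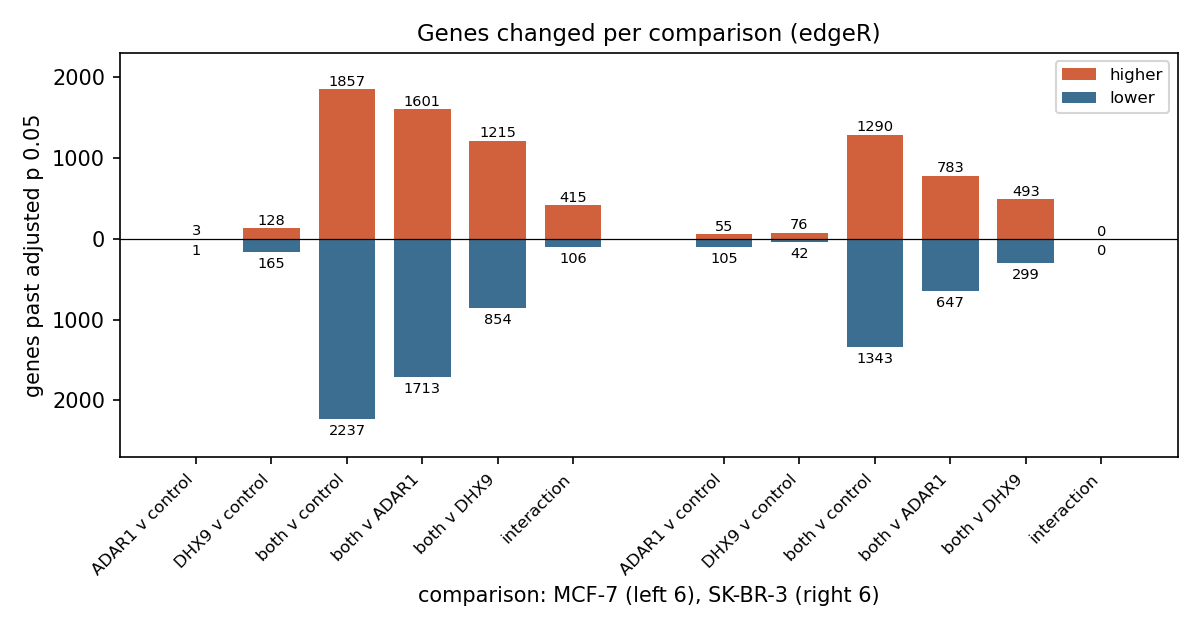
Number of genes past an edgeR adjusted p of 0.05 in 6 comparisons per line; bars above 0 count genes that were higher and bars below 0 genes that were lower. The MCF-7 double knockdown has 1857 and 2237 against its control, and the SK-BR-3 interaction has 0.

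Adding DHX9 knockdown to ADAR1 knockdown in MCF-7 raised 1601 genes and lowered 1713. Interferon-stimulated genes rose in 56 of 58 cases, with OAS2 at 242 ± 34.4 CPM against 3.15 ± 0.722 (6.28 ± 0.24), and 28 of 31 NF-kB targets rose. Cell cycle genes fell in 35 of 44 cases (camera adjusted p = 5.39e-25, 0.0131 with an estimated correlation) and ribosomal protein genes in 57 of 75 (camera adjusted p = 3.1e-24, adjusted p = 0.185 with an estimated correlation). Adding ADAR1 knockdown to DHX9 knockdown raised 1215 and lowered 854, with all 58 interferon-stimulated genes, 27 of 31 NF-kB targets and 16 of 18 antigen presentation genes higher. In this comparison ADAR itself did not pass (276 ± 7.08 against 355 ± 13.2 CPM, -0.36 ± 0.13, adjusted p = 0.0892). TNF, the inflammatory cytokine gene, stood at 25.9 ± 5.81 CPM against 0.18 ± 0.13 in the DHX9 knockdown (7.35 ± 0.71). With library totals alone the splits were 2147 to 1098 (a shift of the median of all genes by 0.117) and 1417 to 620. Leaving out double knockdown replicates 1 and 2 gave 1824 and 1466 genes in the first comparison and 1064 and 816 in the second. The first gave 1810 and 1350 without ADAR1 knockdown replicates 1 and 2, and the second 1187 and 862 without DHX9 knockdown replicates 1 and 2.

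Interferon-stimulated genes in MCF-7 went beyond the sum of the single knockdowns: the interaction was positive for 48 of 58 and negative for 0 (median 3.86, camera adjusted p = 4.6e-217, 2.62e-05 with an estimated correlation). MX1 exceeded the sum by 5.21 ± 0.28 (adjusted p = 6.99e-11), OAS2 by 4.87 ± 0.35 (adjusted p = 5.76e-09) and IFIH1 by 4.02 ± 0.35 (adjusted p = 1.99e-07). So did 20 of 31 NF-kB targets, with TNFAIP2 at 4.87 ± 0.26 (adjusted p = 6.99e-11), 14 of 18 antigen presentation genes, with PSMB9 at 7.16 ± 0.49 (adjusted p = 4.57e-09), 13 of 20 sensing genes, and 3 of 5 interferon genes, with IFNL1 at 6.11 ± 0.94 (adjusted p = 0.000839). Cell cycle genes lay below the sum, 8 of 44 past the threshold (35 adjusted over the list alone; median -0.72, camera adjusted p = 3.4e-25, 0.0132 with an estimated correlation). ADAR had an interaction of 1.18 ± 0.18 (adjusted p = 0.000388) and DHX9 of 0.13 ± 0.27 (adjusted p = 0.933). In all 415 genes were above the sum and 106 below. The 521 became 331 and 297 without double knockdown replicates 1 and 2, 323 and 275 without ADAR1 knockdown replicates 1 and 2, 277 without DHX9 knockdown replicate 2, and 268 without control replicate 2.

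ADAR1 knockdown alone in SK-BR-3 raised 55 genes and lowered 105. DLC1, a brake on Rho GTPases, rose from 2.87 ± 0.3 to 11.5 ± 0.237 CPM (1.99 ± 0.22, adjusted p = 4.41e-05), and GATA3, a luminal transcription factor gene, from 3.73 ± 0.529 to 10.1 ± 2.82 CPM (1.46 ± 0.20, adjusted p = 0.000567). TMEM54 fell from 12.7 ± 0.679 to 2.47 ± 0.115 CPM (-2.36 ± 0.24, adjusted p = 1.82e-05), and GNG4, a G protein subunit gene, fell too (-3.63 ± 0.59, adjusted p = 0.00334). Of 58 interferon-stimulated genes 0 rose and 2 fell (median -0.07, camera adjusted p = 0.505): LAMP3 (-2.21, lost without replicate 1 of either group) and IFITM2 (-0.77, adjusted p = 0.0139, lost without knockdown replicate 1 or either control). MCF-7 identity genes, with GATA3 past the threshold and 4 of 8 adjusted over the list alone, had a median of 0.85 (0.69 without fits near 0 counts; camera adjusted p = 2.64e-07, 0.00942 with an estimated correlation). The p53 targets had 2 of 28 higher (camera adjusted p = 9.68e-07, adjusted p = 0.272 with an estimated correlation), one being CDKN1A, the cell cycle inhibitor, at 169 ± 23.3 against 89.3 ± 0.126 CPM (0.92 ± 0.17, adjusted p = 0.0106). Endoplasmic reticulum chaperones had a median of -0.38 with 0 of 20 passing and 5 adjusted over the list alone (camera adjusted p = 4.54e-10, adjusted p = 0.272 with an estimated correlation). With the replicate block 298 genes were higher and 467 lower, including 2 and 3 interferon-stimulated genes. The 160 became 82 and 103 without replicates 1 and 2 of the knockdown and 62 without control replicate 1.

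DHX9 knockdown alone in SK-BR-3 raised 76 genes and lowered 42. BIN2 was at least 44.2-fold higher, at 5.33 ± 0.775 CPM against 0 counts in the control. C19orf73 rose from 0.884 ± 0.406 to 11.7 ± 4.71 CPM (3.80 ± 0.35, adjusted p = 5.99e-06), DDX43, a helicase gene of the germ line, from 0.273 ± 0.292 to 4.96 ± 0.665 CPM (4.37 ± 0.53, adjusted p = 0.000252), and C1orf54 rose as well (3.23 ± 0.43). ADGRB2, an adhesion receptor gene, fell from 58.3 ± 15.9 to 16.2 ± 4.73 CPM (-1.85 ± 0.25, adjusted p = 0.00118). Of the members of the 17 lists, DHX9 was the 1 that passed, and interferon-stimulated genes had a median of -0.01 (camera adjusted p = 0.738), which turned to 0.05 with library totals alone. Camera called NF-kB targets higher (median 0.37, adjusted p = 0.00196, adjusted p = 0.628 with an estimated correlation) and chaperones lower (median -0.31, adjusted p = 3.43e-05, adjusted p = 0.625 with an estimated correlation). The split was 64 to 57 with RLE size factors, 133 to 211 in DESeq2 and 344 to 524 with the replicate block, which also brought 5 NF-kB targets and 4 estrogen response genes past the threshold upward and gave camera calls to estrogen response (adjusted p = 0.0415), cholesterol synthesis (0.0415) and SK-BR-3 identity genes (0.0383). None of these 3 held with the block and an estimated correlation (adjusted p = 0.241, 0.887 and 0.272). The 118 became 47 and 34 without replicates 1 and 2 of the knockdown, and 24 and 40 without replicates 1 and 2 of the control.

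Interferon-stimulated genes in the SK-BR-3 double knockdown did not rise as a list: 2 of 58 were higher and 8 lower (median -0.03, or 0.01 with library totals alone; camera adjusted p = 0.169). ISG15 stood at 28 ± 16.6 CPM against 13.6 ± 2.88 (1.04 ± 0.40, adjusted p = 0.141) and STAT1 at 59.6 ± 2.2 against 50.6 ± 2.59 (0.24 ± 0.16, adjusted p = 0.422). IFITM2 fell from 147 ± 0.821 to 70.5 ± 5.24 CPM (-1.06 ± 0.15, adjusted p = 0.00013). The 2 higher were RSAD2, at 22 counts against 2 (ratio 9.03, 95% interval 2.22 to 79.2), and TRIM22 (2.61), each lost without double knockdown replicate 1 or control replicate 1. IFNB1 and IFNL1 had 0 counts in all 8 SK-BR-3 libraries, so no induction was detectable at this depth, and 0 of 5 interferon genes passed. Of 20 sensing genes 3 rose (camera adjusted p = 0.241), one being ZNFX1, from 50.2 ± 0.971 to 85 ± 5.71 CPM (0.76 ± 0.15, adjusted p = 0.00203). DDX58 (0.32, adjusted p = 0.565) and EIF2AK2 (0.20, adjusted p = 0.514) did not pass. With the replicate block 7 interferon-stimulated genes were higher and 10 lower, and 6 sensing genes higher and 1 lower. Leaving out control replicate 1 took the 2 higher interferon-stimulated genes to 0, and leaving out double knockdown replicate 1 or control replicate 2 to 1.

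Some NF-kB, stress and p53 genes did rise in these cells. Of 31 NF-kB targets 5 rose and 1 fell, with IRF1 going from 10.1 ± 0.248 to 35.6 ± 14.8 CPM (1.82 ± 0.23, adjusted p = 4.44e-05) and TNFAIP3 from 13.2 ± 4.21 to 57.8 ± 27.4 CPM (2.14 ± 0.29, adjusted p = 0.000272), while RELB, an NF-kB subunit gene, gave 34.8 ± 23 against 13 ± 6.04 CPM (1.43, adjusted p = 0.209). Integrated stress response genes had 3 higher and 3 lower of 35 (camera adjusted p = 0.683), with ATF3 going from 19.8 ± 4.93 to 113 ± 53.5 CPM (2.51 ± 0.34, adjusted p = 0.000311) and PPP1R15A from 20 ± 0.89 to 81.3 ± 44.3 CPM (2.02 ± 0.25, adjusted p = 7.65e-05). Of 28 p53 targets 5 rose, with MDM2, which degrades p53, going from 49.6 ± 0.532 to 117 ± 9.37 CPM (1.24 ± 0.16, adjusted p = 5.48e-05). SNAI2, a repressor of epithelial genes, rose from 9.7 ± 1.21 to 50.4 ± 21.7 CPM (2.37 ± 0.30, adjusted p = 4.44e-05), 1 of 5 mesenchymal and matrix genes that rose while 3 of the 21 fell (camera adjusted p = 0.0541, 0.00666 with the replicate block, and 0.28 with the block and an estimated correlation). Camera called NF-kB targets (adjusted p = 0.0245) and p53 targets (adjusted p = 0.000498) higher, but not with an estimated correlation (adjusted p = 0.568 and 0.4). With the replicate block 9 NF-kB targets, 10 p53 targets and 9 mesenchymal genes were higher.

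In the SK-BR-3 double knockdown some cholesterol synthesis and chaperone genes fell. Of 24 cholesterol synthesis genes 7 fell (14 adjusted over the list alone; median -0.55, camera adjusted p = 4.7e-09), among them LDLR, the receptor that takes up cholesterol, from 1100 ± 43.4 to 604 ± 62.9 CPM (-0.87 ± 0.15, adjusted p = 0.000588), and INSIG1, which holds back sterol synthesis, from 423 ± 20.9 to 172 ± 73.2 CPM (-1.30 ± 0.23, adjusted p = 0.00157). Of 20 chaperones 10 fell (13 adjusted over the list alone; median -0.63, camera adjusted p = 1.27e-08), such as HYOU1, from 575 ± 92.5 to 273 ± 16.9 CPM (-1.08 ± 0.20, adjusted p = 0.00186), a call lost without double knockdown replicate 2. Neither list held with an estimated correlation (adjusted p = 0.305 for each), and the replicate block gave 16 and 15 falls. Antigen presentation genes had 0 higher and 2 lower of 18 (camera adjusted p = 0.0245, adjusted p = 0.505 with an estimated correlation) and ribosomal protein genes 2 lower of 75 (camera adjusted p = 0.00428, adjusted p = 0.689 with an estimated correlation), against 5 and 12 lower with the replicate block.

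The remaining SK-BR-3 lists had few genes past the threshold: cell cycle 4 higher and 2 lower of 44 (camera adjusted p = 0.577), hypoxia and glycolysis 2 and 3 of 24 (0.483), estrogen response 2 and 0 of 24 (0.252), RNA binding and editing 1 and 3 of 23 (0.241), and SK-BR-3 identity 1 and 2 of 8 (0.257). MCF-7 identity genes had 2 of 8 higher, one being GATA3 (1.17 ± 0.20, adjusted p = 0.000786; camera adjusted p = 0.0409, adjusted p = 0.305 with an estimated correlation). CA9, a hypoxia-induced carbonic anhydrase gene, fell from 4.41 ± 0.841 to 0.885 ± 0.266 CPM (-2.32 ± 0.44, adjusted p = 0.0017). The medians of cell cycle and integrated stress response genes, -0.08 and -0.06, turned to 0.00 and 0.02 with library totals alone. Markers gave 1 of 5 fibroblast genes higher (COL1A1, 1.00 ± 0.19, adjusted p = 0.00141), 0 of 2 macrophage and 0 of 2 lymphocyte genes past the threshold, and 1 of 5 endothelial genes lower. With the replicate block cell cycle genes had 6 higher and 11 lower, estrogen response genes 6 higher, SK-BR-3 identity genes 2 and 3, and MCF-7 identity genes 3 higher.

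The largest SK-BR-3 rises included BIN2, at least 58.4-fold higher, ARID3A, a transcription factor gene, from 2.92 ± 1.64 to 43.1 ± 4.91 CPM (3.82 ± 0.25, adjusted p = 9.68e-09), and FBXW10 from 0.625 ± 0.321 to 9.23 ± 2.12 CPM (3.94 ± 0.54, adjusted p = 9.62e-05). SNPH, a mitochondrial anchor in neurons, fell from 3.07 ± 0.121 to 0.138 ± 0.0303 CPM (-4.46 ± 0.66, adjusted p = 0.000185) and SLC22A31, a transporter gene, from 13.8 ± 1.47 to 0.932 ± 0.531 CPM (-3.84 ± 0.37, adjusted p = 2.56e-06). In all 1290 genes were higher and 1343 lower, 489 and 658 of them by at least 2-fold, against 1854 and 1100 with library totals alone and 2449 and 2620 with the replicate block. The 2633 became 658 without double knockdown replicate 2 and 1041 without control replicate 1. The 1 named SK-BR-3 gene whose call the replicate block ended was DDIT3 (adjusted p = 0.0712), a stress-induced transcription factor gene.

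**Figure D4:**
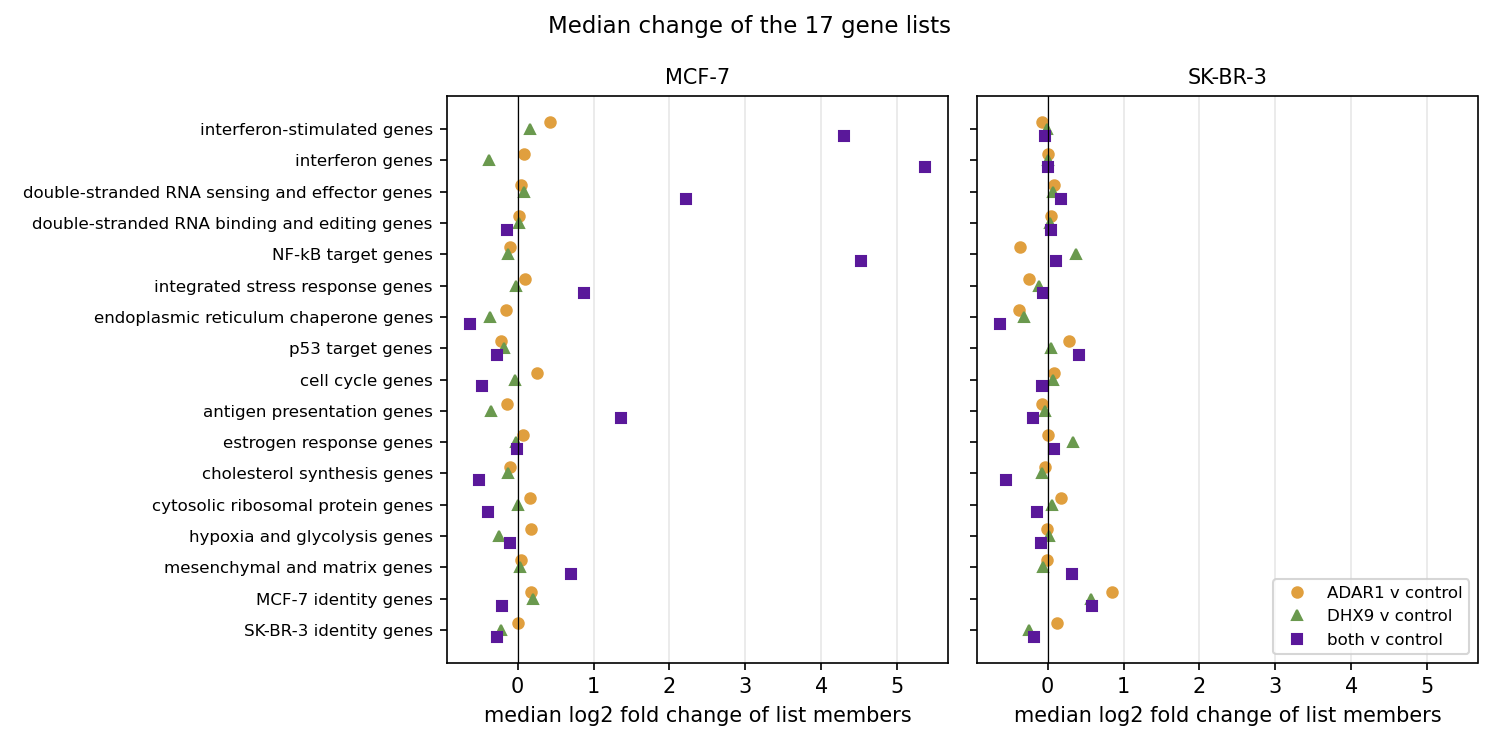
Median log2 fold change of each of 17 gene lists against the control of the same line, for each knockdown; points are medians of fitted values. Interferon-stimulated genes sit at 4.29 in the MCF-7 double knockdown and at -0.03 in that of SK-BR-3.

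Adding DHX9 knockdown to ADAR1 knockdown in SK-BR-3 raised 783 genes and lowered 647. TNFAIP3 (2.59 ± 0.30, adjusted p = 0.000227), IRF1 (1.61 ± 0.23) and 7 other NF-kB targets of 31 rose (camera adjusted p = 1.68e-08, adjusted p = 0.391 with an estimated correlation), and 6 of 24 cholesterol synthesis genes fell, LDLR among them (-0.90 ± 0.15, adjusted p = 0.00108). Adding ADAR1 knockdown to DHX9 knockdown raised 493 and lowered 299, with ARID3A at 43.1 ± 4.91 against 4.53 ± 0.225 CPM (3.25 ± 0.24, adjusted p = 8.51e-08) and 4 of 21 mesenchymal genes higher. Of 58 interferon-stimulated genes 1 was higher and 2 lower in the first comparison, and 1 and 3 in the second. The replicate block gave 1914 and 1918 genes in the first and 1437 and 1225 in the second, and library totals alone gave 1171 and 522 in the first. The block also gave camera calls in the first to antigen presentation (adjusted p = 0.0457), mesenchymal (0.0197) and SK-BR-3 identity genes (0.0443), which an estimated correlation ended (0.623, 0.496 and 0.496). The first count of 1430 became 2249 and 170 without double knockdown replicates 1 and 2 and 383 without ADAR1 knockdown replicate 1. The second, 792, became 1375 and 68 without double knockdown replicates 1 and 2, and 162 and 260 without DHX9 knockdown replicates 1 and 2.

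In SK-BR-3 the edgeR fit of all 16 libraries without the replicate block detected no departure from the sum of the single knockdowns. There 0 genes passed, with 1764 at an unadjusted p under 0.05. DESeq2 gave 62 genes, and edgeR with the replicate block gave 116 above and 56 below the sum. On simulated counts the fit without the block found 18% of 2-fold changes in this interaction. ADAR had an interaction of 0.34 ± 0.18 (adjusted p = 0.806) and DHX9 of -0.30 ± 0.27 (adjusted p = 0.941). Camera placed NF-kB targets above the sum (median 0.29, adjusted p = 0.000504) and ribosomal protein genes (median -0.36, adjusted p = 7.64e-17) and cholesterol synthesis genes (median -0.34, adjusted p = 2.84e-06) below it, each lost with an estimated correlation (adjusted p = 0.512 for all 3). With the replicate block 4 NF-kB and 3 mesenchymal genes were above the sum, and antigen presentation genes gained a camera call (adjusted p = 0.045, but 0.759 with an estimated correlation). Without double knockdown replicate 1 the count of 0 became 161, without ADAR1 knockdown replicates 1 and 2 it became 5 and 2, and without control replicate 2 it became 2.

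The double knockdown changed 1250 genes differently in the 2 lines, 797 more upward in MCF-7 and 453 more upward in SK-BR-3. Of the interferon-stimulated genes 49 of 58 were more upward in MCF-7 (median difference 4.37, camera adjusted p = 2.8e-207, 3.09e-05 with an estimated correlation), among them OAS3 by 5.18 ± 0.22 (adjusted p = 9.82e-13) and MX1 by 5.91 ± 0.30. So were 21 of 31 NF-kB targets, with TNFAIP2 by 5.87 ± 0.25, 15 of 18 antigen presentation genes, with NLRC5 by 5.42 ± 0.24, and 13 of 20 sensing genes, with IFIH1 by 3.60 ± 0.35. C3, a complement protein gene, differed by 8.34 ± 0.33 (adjusted p = 9.69e-13). More upward in SK-BR-3 were MDM2 (-1.30 ± 0.22) and 4 other p53 targets, with 1 more upward in MCF-7 (camera adjusted p = 3.74e-05, adjusted p = 0.217 with an estimated correlation), and GATA3 (-1.50 ± 0.26). ADAR itself differed by 1.68 ± 0.18 (adjusted p = 2.67e-06) and DHX9 by 0.15 ± 0.27 (adjusted p = 0.875). Of the cell cycle genes 9 of 44 were lower in MCF-7 relative to SK-BR-3 (camera adjusted p = 4.35e-08, adjusted p = 0.19 with an estimated correlation), and for chaperones and cholesterol synthesis genes 0 differed. The 1250 became 792 and 795 without MCF-7 double knockdown replicates 1 and 2, 790 without MCF-7 control replicate 2 and 787 without SK-BR-3 control replicate 1, and 2929 with the replicate block.

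The interaction differed between the lines for 150 genes, 145 of them higher in MCF-7, including 34 of 58 interferon-stimulated genes (median 3.58), such as PARP10 (4.47 ± 0.30) and OAS3 (4.45 ± 0.30, adjusted p = 1.26e-08), and 13 each of the 31 NF-kB targets and 18 antigen presentation genes. The 5 lower in MCF-7 were SPDEF, IGSF1, TRPS1, BMP7 and STK39, of which SPDEF, an epithelial transcription factor gene, differed by -3.05 ± 0.51. STK39 lost its call without SK-BR-3 double knockdown replicate 1, BMP7 without that or any of 4 other SK-BR-3 libraries, and TRPS1 without any of 14 libraries. The replicate block gave 444. For DHX9 knockdown alone 40 genes differed, 19 and 21, with RASGRP1 (2.72 ± 0.35, adjusted p = 0.00114) and C3 (2.23 ± 0.31, adjusted p = 0.00204) more upward in MCF-7; the count was 339 with the replicate block. It became 17 and 15 without MCF-7 DHX9 knockdown replicates 1 and 2, 26 and 15 without MCF-7 control replicates 1 and 2, 61 without SK-BR-3 double knockdown replicate 1 and 18 without SK-BR-3 control replicate 1.

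For ADAR1 knockdown alone 9 genes differed between the lines: TMEM54, PTPRE, OLFM1, HEG1, ANTXR1, PCDH1, PLEKHG1 and PDGFA more upward in MCF-7, and DLC1 more upward in SK-BR-3. TMEM54 differed by 2.20 ± 0.32 (adjusted p = 0.00955), a call lost without MCF-7 knockdown replicate 1 or MCF-7 control replicate 2. The other 8 each lost theirs without MCF-7 knockdown replicate 1 or SK-BR-3 control replicate 1, and 7 of them, all but PTPRE, also without 4 or more other libraries. The count was 140 with the replicate block. Among MCF-7 libraries it became 0 and 2 without knockdown replicates 1 and 2, and 4 and 1 without control replicates 1 and 2. Among SK-BR-3 libraries it became 20 without either double knockdown library, 15 and 16 without DHX9 knockdown replicates 1 and 2, and 2 without control replicate 1. The difference for ADAR did not pass (0.86 ± 0.18, adjusted p = 0.122), but passed with the replicate block (adjusted p = 0.00463), with no filter (0.0244) and in DESeq2 (3.3e-05).

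DHX9 knockdown alone raised 23 genes in both lines, where 0.362 would be shared by chance. The chance values here take the calls of the lines as independent over all tested genes. Detection depends on expression and the lines share 1 fit, so sharing by chance may be higher. DHX9 knockdown lowered 16 in both, where chance gives 0.258, and 0 went opposite ways, for which no chance value was computed. Besides BIN2, C19orf73 and C1orf54 the shared rises included ZNF91, a zinc finger repressor gene (1.67 ± 0.19 in MCF-7 and 1.13 ± 0.19 in SK-BR-3, the latter lost without knockdown replicate 1 or control replicate 2). Others were the tumour suppressor gene NF2 (0.96 ± 0.16 and 0.78 ± 0.16) and the calcium channel gene CACNA1A (2.35 ± 0.43 and 2.36 ± 0.52). The shared falls included DHX9, FTL, the ferritin light chain gene (-1.16 ± 0.14 and -0.88 ± 0.14, the latter lost without knockdown replicate 2), and the stress granule gene G3BP2 (-0.72 ± 0.14 in each line). In SK-BR-3 the calls of NF2, CACNA1A and G3BP2 were lost without any 1 of the 4 control and DHX9 knockdown libraries. In MCF-7 that held for G3BP2, while NF2 lost its call without knockdown replicate 2 or control replicate 2, and CACNA1A without knockdown replicate 1 or either control. The double knockdown raised 377 genes and lowered 588 in both lines, against 89.2 and 112 by chance on the same assumption, with 116 going opposite ways. ADAR1 knockdown alone had 1 shared gene, ADAR. Across the 26867 genes, which are not independent replicates, the log2 changes of the lines correlated at r = 0.0164 (rho 0.0757) for ADAR1 knockdown, 0.0797 (0.138) for DHX9 knockdown, 0.109 (0.196) for the double knockdown and -0.00828 (0.082) for the interaction. Over the 9945 genes above 8 CPM r was 0.298, 0.322, 0.421 and 0.355 (rho 0.3, 0.355, 0.516 and 0.447).

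In the MCF-7 double knockdown 11 of 1115 repeat subfamilies rose and 7 fell: the satellite ACRO1 rose (2.61 ± 0.25, adjusted p = 1.46e-21), as did MLT1-int, of an old endogenous retrovirus family (1.89 ± 0.27, adjusted p = 8.8e-10), while LTR1B (-1.19 ± 0.18, adjusted p = 1.48e-08) and the satellite SATR1 (-1.06 ± 0.17, adjusted p = 7.43e-08) fell. Alu elements, a main source of double-stranded RNA that ADAR1 edits, had a median change of -0.01 over 51 subfamilies, L1 elements -0.05 over 131 and ERV1 elements 0.06 over 295. ADAR1 knockdown alone had 0 higher and 3 lower, namely SATR1 (-0.98 ± 0.17), LTR1B (-0.94 ± 0.18) and SATR2 (-0.92 ± 0.17). SATR1 and SATR2 lost that call with the repeats' own totals (adjusted p = 0.998 for SATR2). DHX9 knockdown alone had 3 higher, with MamRep4096 at 1.19 ± 0.19 (adjusted p = 6.4e-07), ACRO1 at 1.33 ± 0.26 (lost without knockdown replicate 1 or control replicate 2) and LTR73 at 1.00 ± 0.22 (lost without knockdown replicate 2 or either control). The interaction had 3 higher. Of these MLT1-int (2.31 ± 0.41, adjusted p = 2.19e-05) kept its call without each library. ACRO1 (adjusted p = 0.0476) and LTR103_Mam (adjusted p = 0.0366) did not. The double knockdown's 18 dropped without its replicate 2, and became 36 with the repeats' own totals. The ADAR1 knockdown's 3 became 5 without its replicate 1 and 0 without control replicate 2, and the DHX9 knockdown's 3 became 1 without control replicate 2. The interaction's 3 became 1 without DHX9 knockdown replicate 2, control replicate 1, or any ADAR1 or double knockdown library.

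In SK-BR-3 the median subfamily of each repeat family examined was higher than control with DHX9 knockdown, alone or with ADAR1. Summed counts did not all follow. Those of DNA elements changed by -0.12 and -0.30 (DHX9 and double knockdown) and those of ERVK by -0.08 in the double knockdown. With DHX9 knockdown alone the median of all 1115 subfamilies was 0.26, with Alu at 0.31, L1 at 0.25, ERV1 at 0.26 and ERVL at 0.26, and in the double knockdown it was 0.25, with Alu at 0.22 and L1 at 0.26. Scaled by the repeats' own totals these overall medians were 0.00 and 0.01. That scaling holds the typical subfamily near 0 in each comparison, so it cannot decide whether all repeats shifted together. ADAR1 knockdown alone in SK-BR-3 also left medians above control, though less far: 0.09 over all subfamilies and 0.05 for Alu. In MCF-7 the median of all subfamilies was -0.16 with ADAR1 and 0.08 with DHX9 knockdown. Summed over all subfamilies, the change with DHX9 knockdown in SK-BR-3 was 0.18, under the larger replicate SD of 0.25 on the log2 scale. Repeats took 16.2% and 20.2% of the element table in the 2 DHX9 knockdown libraries against 15.5% and 16.1% in the controls. Few subfamilies passed: 4 rose with DHX9 knockdown alone, HERV1_I-int (1.99 ± 0.24, adjusted p = 3.06e-13), LTR16D1 (1.62 ± 0.31, adjusted p = 8.18e-05), ACRO1 (1.38 ± 0.33, adjusted p = 0.0101) and HERVFH21-int (1.36 ± 0.29, adjusted p = 0.000999). HERV1_I-int and ACRO1 lost this with the repeats' own totals (adjusted p = 0.253 for each), and HERVFH21-int without either control. The double knockdown raised 7 and lowered 2, BLACKJACK (-0.70 ± 0.17, adjusted p = 0.00783) and MER83B-int (-0.88 ± 0.19, adjusted p = 0.00101). BLACKJACK lost its call with library totals alone (adjusted p = 0.129) and MER83B-int with the repeats' own totals (adjusted p = 0.198). ADAR1 knockdown alone lowered 4, MER83B-int, LTR46-int, BLACKJACK and MER72, and the interaction had 0, with 23 at an unadjusted p under 0.05.

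SK-BR-3 repeat counts with the replicate block were 62 higher and 2 lower for DHX9 knockdown, 80 and 10 for the double knockdown, and 3 and 7 for ADAR1 knockdown. The 4 of the DHX9 knockdown became 446 without its replicate 1 and 2 without either control. The 9 of the double knockdown became 1 without its replicate 2, 2 and 5 without control replicates 1 and 2, and 20 without either DHX9 knockdown library. The 4 of the ADAR1 knockdown became 2 and 1 without its replicates 1 and 2, 0 without control replicate 1 and 9 without either DHX9 knockdown library.

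**Figure D5:**
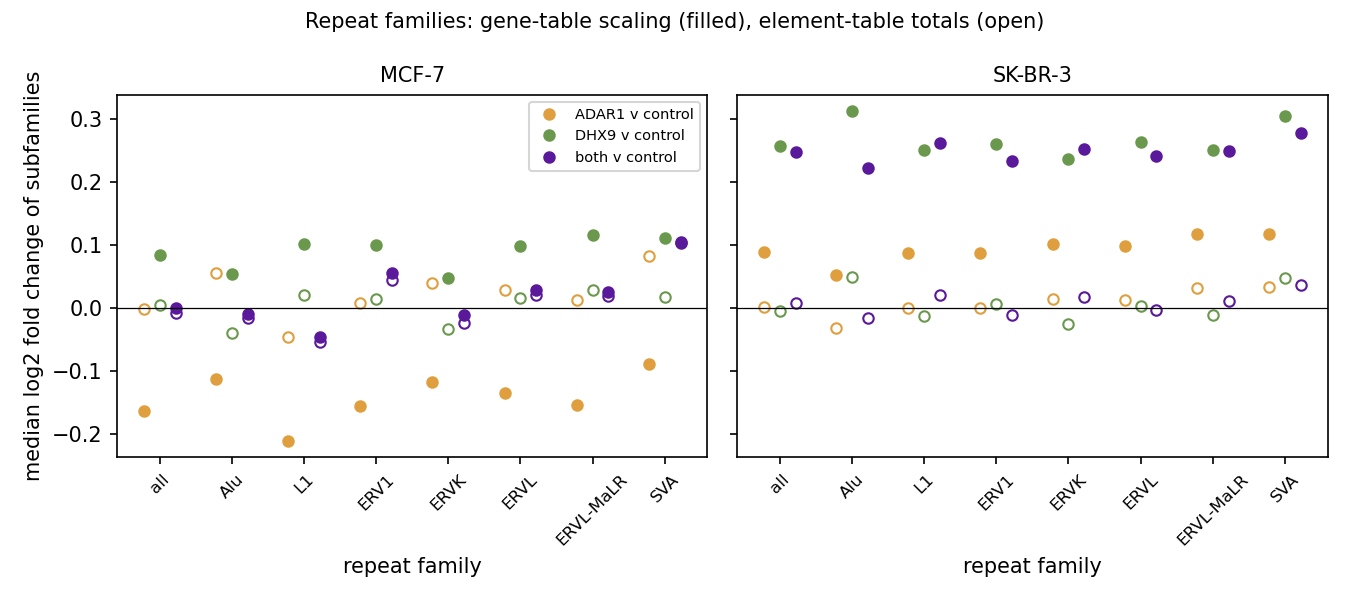
Median log2 fold change of the subfamilies of each repeat family, by line and knockdown. Filled points use the scaling of the gene table. Open points use the repeats' own totals, called element-table totals in the figure title, a scaling that centres the repeats. In SK-BR-3 with DHX9 knockdown the Alu median is 0.31 with the scaling of the gene table.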

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

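The tests for immune cells, for a weaker knockdown and for pseudogene reads were chosen after the results they address were seen, and the others before. Tests of the difference between the lines picked out 9 genes for ADAR1 knockdown, 40 for DHX9 knockdown, 1250 for the double knockdown and 150 for the interaction. In the double knockdown 4 gene lists differed between the lines in camera both at the preset and at an estimated correlation (others at the preset one alone), with median differences, MCF-7 minus SK-BR-3, of 4.37 for interferon-stimulated genes, 1.74 for double-stranded RNA sensing and effector genes, 3.30 for NF-kB targets and 1.60 for antigen presentation genes.

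Interferon-stimulated genes rose in the MCF-7 double knockdown (57 of 58) and not as a list in that of SK-BR-3 (2 higher and 8 lower). Immune cells mixed into the MCF-7 libraries are argued against by 5 of 6 of their markers staying under 0.1 CPM in both, although a first criterion, the mean of the 6, had left this open at 0.593 and 0.51 CPM (limits 5 and 0.5), carried by CSF1R at 3.56 and 2.98 CPM against 1.27 in the controls. Of all 15 immune markers in the fixed lists 9 were under 0.1 CPM in both libraries, PTPRC (0 counts) among them, and LYZ stood at 0 and 0.146 CPM. CD79A, which the 6 leave out, rose to 5.49 CPM from 0.663, which these markers do not explain. CD14 (mean 1.14 against 0.508 CPM in the controls) and CD8A (2 against 0.985) were also higher, while CD68, LYZ, AIF1, CD3E, MS4A1 and NKG7 were lower. A weaker knockdown in SK-BR-3 would leave more transcript there. For DHX9 the log2 change differed, MCF-7 minus SK-BR-3, by 0.149 (SE 0.271, so within its error of 0). For ADAR it differed by 1.68 (SE 0.182), but interferon itself induces this gene, so its level in the MCF-7 double knockdown cannot decide the question. With ADAR1 knockdown alone ADAR differed by 0.86 (adjusted p = 0.122), again with less transcript left in SK-BR-3. That difference passed with the replicate block, with no filter and in DESeq2. Protein was not measured. Of 18 sensing and signalling genes 0 were missing at the transcript level in SK-BR-3 (under 1 CPM in both controls and at least 4-fold below MCF-7), and a difference between the lines in how double-stranded RNA is made, sensed or signalled, proteins included, may underlie the pattern, a hypothesis that no test here separates from an effect of one hairpin.

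DHX9 knockdown raised 23 genes in both lines. Read-through from an expressed neighbour may account for part of them: 60.9% (14 of 23) have a gene of at least 1 CPM on the same strand ending within 10 kb upstream or overlapping, against a median of 26.1% and a 95th percentile of 39.1% in 10000 random lists matched on expression (permutation p = 8e-04, one-sided for a larger share, as are those that follow). The same permutation test was run on the rises of MCF-7 (28.9%, permutation p = 0.15) and of SK-BR-3 (38.2%, 0.0099), which include the 23, on the shared falls (25%, 0.56) and the shared rises of the double knockdown (24.9%, 0.21), and on the opposite strand, where the share was 56.2% against a random median of 37.5% for the shared falls and below the random median for the others: 30.4% against 39.1% (the 23 genes), 23.4% against 39.8% (MCF-7), 28.9% against 39.5% (SK-BR-3) and 31.3% against 37.9% (double knockdown). The random lists were matched on expression alone, not on gene type. Some of the 23, such as AL078581.2 and RPS18P9, lie side by side and are not independent draws. These permutation p-values may therefore be too small. Reads from parent genes of pseudogenes are argued against for most of the 23, since 1 is annotated as a pseudogene. Reads shared between gene copies of other kinds were not tested. For the 9 without a same-strand neighbour, BIN2 and C19orf73 among them, and for a change in the RNA itself, the question stays open. Of the 14 neighbours TRIM16L alone changed, in MCF-7 (1.16, adjusted p = 0.000802).

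In SK-BR-3 the difference between replicates 1 and 2 was shared across groups (r from 0.1 to 0.22 across genes in 6 pairs of groups). GC content as its cause is argued against by rho across genes of -0.0256 in the ADAR1 knockdown group, the value nearest 0, with -0.0893 to 0.108 over the 4 groups, since a shared cause would act in each. Transcript length is argued against by rho of 0.0213 in the same group, with -0.194 to 0.0944 over the 4. A shared culture, day or library batch is not given by the labels and stays open, and no biological explanation was tested.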

How the results depend on the processing

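The alternatives chosen after the data were seen were camera with RLE factors, with library totals or with the replicate block and an estimated correlation together, and the repeat counts with RLE factors, library totals or 1 line alone. No named gene, repeat or list reversed past its threshold under the alternatives that were run, and RLE size factors moved no count by over 1.5 times. The balance of genes higher and lower was not part of that check, and it did turn in some comparisons. In the SK-BR-3 DHX9 knockdown 76 higher and 42 lower became 133 and 211 in DESeq2. In the MCF-7 double knockdown 1857 and 2237 became 2428 and 1562 with library totals alone. Among named genes, repeats and lists, calls lost and gained numbered 6 and 5 with RLE factors, 23 and 1 with library totals alone, 8 and 2 in DESeq2, and 5 and 1 with no filter. They numbered 15 and 0 with 1 CPM in 2 libraries, 58 and 1 with the line alone, 11 and 0 with the repeats' own totals, and 1 and 19 with the replicate block. Leaving out 1 library lost 507 of them and gained 1, summed over the libraries. Of the list calls 41 were lost with fry, which gained 7, 64 with an estimated correlation and 66 when the block was added to it. The calls that held with an estimated correlation were those of interferon-stimulated, interferon, sensing, NF-kB and antigen presentation genes in the MCF-7 double knockdown, against control and each single, and in its interaction, mesenchymal genes in these but not the interaction, cell cycle genes in the double against ADAR1 knockdown and in the interaction, MCF-7 identity genes with ADAR1 knockdown in SK-BR-3, and sensing, NF-kB, antigen presentation and interferon-stimulated genes in the differences between lines for the double knockdown and interaction. Depth and 2 replicates limit what could be seen: on simulated counts 2-fold changes were found at 52% and 57% (MCF-7, SK-BR-3) and at 18% in both interactions, and 1.5-fold and 2-fold changes of repeats at 48% and 74%. The cause was not tested for any value below, except that a stricter threshold cannot call more genes by construction. Fewer libraries gave fewer calls in some comparisons and more in others. Counts below are of genes higher and lower together, against control unless stated.

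DESeq2 gave 59 genes for ADAR1 and 542 for DHX9 knockdown and 969 for the interaction in MCF-7. In SK-BR-3 it gave 357 and 344 for the single knockdowns, 2419 and 1634 for the double against the ADAR1 and DHX9 knockdowns, and 62 for the interaction. Between lines it gave 52, 142 and 256 for ADAR1, DHX9 and the interaction. It called 2 higher interferon-stimulated genes with ADAR1 knockdown in MCF-7 and 1 in SK-BR-3, and 6 repeats with DHX9 knockdown in MCF-7, 2 and 7 with ADAR1 and DHX9 knockdown in SK-BR-3.

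With no filter MCF-7 had 84, 622 and 909 genes (ADAR1, DHX9, interaction), SK-BR-3 441, 413 and 117, with 2152 and 1369 for the double against the ADAR1 and DHX9 knockdowns, and the lines differed in 111, 214 and 324. Higher interferon-stimulated genes were then 4 and 3 in MCF-7 (ADAR1, DHX9) and 2 in SK-BR-3 (ADAR1).

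At an adjusted p under 0.01 MCF-7 had 1, 101 and 2252 genes for ADAR1, DHX9 and double knockdown, 1680 and 963 for the double against each single, and 249 for the interaction. SK-BR-3 had 54, 26, 1189, 506 and 210, and the lines differed in 2, 11, 576 and 97. Higher interferon-stimulated genes were 0 with ADAR1 knockdown in MCF-7 and 1 in the SK-BR-3 double knockdown, and 1 repeat kept the MCF-7 interaction.

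With each line fitted alone MCF-7 had 53 and 748 genes for the single knockdowns, 4974 and 3596 for the double against each, and 1327 for the interaction, and SK-BR-3 45, 5, 1674, 505 and 123. Higher interferon-stimulated genes were 8 and 4 (MCF-7 ADAR1, DHX9) and 1 (SK-BR-3 double), and the MCF-7 interaction had 1 repeat. The r between lines became 0.047, 0.193 and 0.216 (ADAR1, DHX9, double), against 0.0386, 0.114 and 0.151 with a filter of 1 CPM in 2 libraries and 0.0245 and 0.0909 (ADAR1, DHX9) in DESeq2.

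In MCF-7, where replicate differences correlated above the limit of 0.1 in some pairs of groups and below it in others, the replicate block gave 151, 1129 and 6333 genes, 5591 and 4316 for the double against each single and 1722 for the interaction, and SK-BR-3 765, 868, 5069, 3832, 2662 and 172. The lines differed in 140, 339, 2929 and 444. Higher interferon-stimulated genes were 8 and 6 (MCF-7 ADAR1, DHX9), and 2 and 7 (SK-BR-3 ADAR1, double). Repeats were 7, 35 and 5 (MCF-7 DHX9, double, interaction) and 10, 64 and 90 (SK-BR-3 ADAR1, DHX9, double). The block in MCF-7 also called interferon-stimulated, sensing and mesenchymal genes with DHX9 knockdown (adjusted p = 0.024, 0.0211 and 0.00446), estrogen response and MCF-7 identity genes in the double against ADAR1 knockdown (0.0458 each), and MCF-7 identity genes in the double against DHX9 knockdown (0.0346). With the block and an estimated correlation none of these held (0.583, 0.263, 0.231, 0.12, 0.136 and 0.131 in that order). In SK-BR-3 the block changed no other call of a named gene or list than those given with the results. The repeats' own totals gave 1 and 36 repeats (MCF-7 ADAR1, double) and 2 and 2 (SK-BR-3 ADAR1, DHX9). Library totals alone gave 1 for the MCF-7 interaction and 2 for SK-BR-3 ADAR1 knockdown.

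Leaving out each library in turn gave these ranges of gene counts. MCF-7 had 1 to 8 for ADAR1, 38 to 253 for DHX9, 1952 to 3863 for the double, 1350 to 3114 and 816 to 2028 for the double against each single, and 268 to 361 for the interaction. SK-BR-3 had 62 to 177, 24 to 162, 658 to 2900, 170 to 2249, 68 to 1375, and 0 to 161. The lines differed in 0 to 20 (ADAR1), 15 to 61 (DHX9), 787 to 1364 (double) and 115 to 176 (interaction). Higher interferon-stimulated genes ranged over 0 to 1, 0 to 1, 55 to 57 and 37 to 45 in MCF-7 (ADAR1, DHX9, double, interaction) and 0 to 2 in the SK-BR-3 double knockdown, with 0 in its single knockdowns and interaction. Repeats ranged over 0 to 5, 1 to 4, 11 to 21 and 1 to 4 in MCF-7 and 0 to 9, 2 to 446, 1 to 20 and 0 in SK-BR-3. The r between lines ranged over 0.00288 to 0.0223 (ADAR1), 0.0509 to 0.0808 (DHX9) and 0.0764 to 0.116 (double). The lowest MCF-7 gene counts came without control replicate 2 (38 for DHX9, 1952 for the double, 268 for the interaction), ADAR1 knockdown replicate 2 (1350) and double knockdown replicate 2 (816), and the 8 for ADAR1 without control replicate 1. In SK-BR-3 62 and 24 came without control replicate 1, 658, 170 and 68 without double knockdown replicate 2, and 2249, 1375 and 161 without double knockdown replicate 1. Between lines the 0 came without MCF-7 ADAR1 knockdown replicate 1, 20 without either SK-BR-3 double knockdown library, 15 without MCF-7 DHX9 knockdown replicate 2 or control replicate 2, 61 without SK-BR-3 double knockdown replicate 1 and 787 without SK-BR-3 control replicate 1. The 446 repeats came without SK-BR-3 DHX9 knockdown replicate 1 and the 1 of its double knockdown without replicate 2 of that group. The other libraries that moved a count by over 1.5 times are named with the results.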

Other observations

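The values here were chosen after the data were seen, and none was part of a fixed comparison. Most genes of the sensing pathway were expressed in both lines before any knockdown. In control cells IFIH1 stood at 11.2 ± 0.809 CPM in MCF-7 and 6.88 ± 1.9 in SK-BR-3, DDX58 at 8.8 ± 1.42 and 4.74 ± 0.381, MAVS at 479 ± 51.4 and 200 ± 7.47, and IRF3, which switches on interferon genes, at 114 ± 0.811 and 43.7 ± 3.84 (SD, n = 2 each). TLR3, the endosomal sensor of double-stranded RNA, had 0.0241 ± 0.0341 CPM in MCF-7 and 11 ± 2.31 in SK-BR-3, and IFNLR1, a receptor chain for type III interferon, 1.67 ± 0.142 and 6.13 ± 1.28. These baseline differences between the lines were not tested.

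Some genes raised by DHX9 knockdown alone in both lines were also higher than control in the double knockdown. The log2 change in the double knockdown was 4.26 in MCF-7 and 3.75 in SK-BR-3 for C19orf73, 2.60 and 3.41 for C1orf54, and 1.18 and 1.41 for ZNF91. The difference between the double and the DHX9 knockdown did not pass for these 3 genes in MCF-7 (adjusted p = 0.751, 0.781 and 0.114 in that order) or SK-BR-3 (0.999, 0.885 and 0.516), which does not show that the changes were equal. In the double knockdown the calls of these 3 genes against control held without each library in turn. That of ZNF91 with DHX9 knockdown alone in SK-BR-3 did not.

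A look at GC content in every group showed a relation in MCF-7. Across 9933 genes the log2 difference between replicates 1 and 2 followed transcript GC with rho 0.612 in the double knockdown and 0.539 in the DHX9 knockdown, against 0.00559 in the ADAR1 knockdown and -0.00589 in the control. Transcript length gave -0.101, -0.04, 0.182 and -0.0131 in the same order. The log2 changes against control followed GC with rho -0.22 for DHX9 knockdown and -0.1 for the double knockdown in MCF-7, and -0.137 and -0.185 in SK-BR-3. No GC correction was run, so the calls in these groups were not checked for it.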
